A study of Homo sapiens with 8 samples.

How the data were processed

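The series measured where 2 proteins sit on chromatin in HCT-116 cells, a human colorectal carcinoma line, by CUT&RUN. In this assay an antibody directs a nuclease to its target in permeabilised cells, and the DNA released around the target is sequenced. Antibodies were directed against Flag-tagged wild type actin (ACTB) and against BRG1, the ATPase encoded by SMARCA4 that drives SWI/SNF chromatin remodelling complexes. Each antibody was used in 1 library of control cells and in 2 libraries of cells without SETD3, numbered KO1 and KO2, and each arm had 1 IgG library of control cells as a negative control. The title of the Flag arm IgG library also holds the word Empty. The labels do not say whether its cells carried the Flag-actin construct. SETD3 is the histidine methyltransferase of actin. The labels do not say whether KO1 and KO2 are separate clones or separate cultures, and no library was repeated.

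The files analysed were 8 peak lists, called per library. Per the submitters' processing notes, the genome build was hg38 and the tools named were Trim Galore 0.4.5, FastQC 0.12.0, BWA, SAMtools, deepTools, bedtools 2.30.0, MACS2 and SEACR, with no order or settings. The deposited lists have the 6-column layout of SEACR, a peak caller for CUT&RUN, and hold the total signal and the maximum signal of each peak. The names the authors gave the lists carry the word stringent, with a threshold of 0.01 for the antibody libraries and 0.005 for the IgG libraries. A numeric SEACR threshold keeps that top fraction of signal blocks of a library, so the number of peaks does not measure binding.

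The normalisation of the deposited signal values is not given in the sources used here. Maximum signals were whole multiples of a fixed step in every library, for 100% of the values below 200 steps within a tolerance of 0.05 steps. The step was 21.5 in the Flag-actin control, 9.69 and 8.40 in Flag-actin KO1 and KO2, 6.61 in the Flag arm IgG, 4.38 in the BRG1 control, 11.5 and 9.09 in BRG1 KO1 and KO2, and 4.73 in the BRG1 arm IgG library. If signal was scaled to depth, a larger step means fewer reads, and the Flag-actin control and the BRG1 KO libraries were then the shallowest of their arms. At 9585 sites held by all 8 lists, the median maximum signal relative to the BRG1 arm IgG library was 3.94 in the Flag-actin control and between 0.973 and 1.16 in the others. Signal values were therefore used mainly to rank peaks within a list. They were compared between lists for the sums at ACTB, for the lowest total signal of each list, and for strong BRG1 control peaks, which were chosen by the lowest total signal of a KO list.

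Peaks on chromosomes 1 to 22, X and Y were kept, which left out between 2.11% and 4.04% of each list. Overlaps of at least 1 bp between lists were computed in Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3. A control peak was called lost in both when it overlapped no peak of either KO list. A region gained in both was a merged region held by both KO lists with no control peak. For genes, lost or gained in both refers to the presence of any gene-end peak in a list, so the peaks of the KO lists at a gained gene need not overlap. Random overlap was taken from 100 circular shifts of the peaks along each chromosome. Such shifts do not keep peaks near gene ends, so an excess over them does not by itself show shared binding. The interval functions were tested on simulated data against bedtools 2.31.1, with 0 disagreements over 60927 intervals.

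Gene positions came from the RefSeq gene table of assembly GRCh38, the same build as hg38, for 20037 protein-coding genes. This table gives no strand, exons or UTRs. The promoter windows planned before the data were examined were therefore replaced by gene-end windows, within 1 kb of either annotated end of a gene. Each such window holds a transcription start or a transcript end, and peaks were not assigned to exons, introns or UTRs. For 21 gene lists fixed before the data were examined, the share of genes with a gene-end peak was compared between control and KO. The difference was ranked among 10000 random lists of the same size, matched on the mean signal rank over the 3 libraries. All 830 list entries matched a symbol. In simulated BRG1 lists of 60 genes, with a loss of 40% of the KO peaks planted, 56% of 50 lists fell below the central 95% of random lists, and 4% of 150 lists with no planted loss fell outside it. The simulated KO libraries kept more of the control genes than the data did, and at a rate that did not depend on signal. In the data 5581 of 6721 BRG1 control genes had no gene-end peak in KO1 and 4418 had none in KO2. The 56% is therefore not the power of the comparison in these data.

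The genes named in the text followed a rule written before the data were examined, applied to peaks without overlap with the IgG list of the same arm. It took, for each antibody, the 10 genes with the highest signal lost in both KO libraries, the 10 with the highest mean rank gained in both, the 5 with the highest mean rank in all 3, at most 4 members of each list in each direction, and 7 genes fixed in advance (ACTB, ACTG1, SETD3, SMARCA4, SMARCA2, MYC and CDH1). Genes outside the rule are named as chosen after their values were seen.

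With 1 control and 2 KO libraries per antibody, a test would rest on 1 degree of freedom and on the control varying like the KO libraries. None was made, and no p-value is given. KO values are given per library, or as mean ± SD over 2 libraries, and no spread is known for the control. Shares carry exact Clopper-Pearson 95% intervals from scipy 1.17.1, which cover counting error only. Read numbers were not used here, so the depth behind each peak is unknown beyond the step above. Alternatives fixed in advance were the removal of peaks shared with IgG, equal-length lists made of the strongest peaks, the upper part of each list by total signal, 50% of a peak covered, sharing within 1 kb, all contigs, gene-end windows of 3 kb and 500 bp, another matching of random lists, and leaving out each KO library. Figures were drawn with matplotlib 3.10.9.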

Results

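The data comprised 8 CUT&RUN libraries of HCT-116 colorectal carcinoma cells. For Flag-tagged actin there were 1 control and 2 SETD3 knockout libraries, with 38902 peaks in the control, 27249 in KO1 and 35892 in KO2. For BRG1, the ATPase of SWI/SNF remodellers, the control list held 53270 peaks, KO1 23784 and KO2 32038. The IgG lists held 20303 peaks in the Flag arm and 24755 in the BRG1 arm. Peaks covered 8.43 Mb in the Flag-actin control against 1.91 and 3.66 Mb in its KO libraries, and 9.29 Mb in the BRG1 control against 1.47 and 2.48 Mb. Median peak width was 220, 50 and 90 bp for Flag-actin control, KO1 and KO2, and 140, 40 and 40 bp for BRG1. No pair of lists was a copy, since at most 4 peaks of any pair shared both position and total signal.

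IgG background made up a larger part of the KO lists than of the control lists. Of the BRG1 peaks, 34.9% overlapped an IgG peak in the control (95% interval 34.5 to 35.3), 70.5% in KO1 (69.9 to 71.1) and 58.7% in KO2 (58.2 to 59.3). For Flag-actin these shares were 32.7% (32.2 to 33.2), 50.5% (49.9 to 51.1) and 39.2% (38.7 to 39.7). The numbers of peaks that overlapped IgG differed less, at 18581, 16772 and 18818 for BRG1 and 12724, 13768 and 14054 for Flag-actin. The peaks without such overlap were fewer in the KO lists, at 34689, 7012 and 13220 for BRG1 and 26178, 13481 and 21838 for Flag-actin. Narrow peaks of up to 50 bp overlapped IgG in 73.6% to 92.4% of cases over the 6 antibody libraries, and peaks wider than 100 bp in 5.66% to 10.8%. Within a width class the KO lists were not uniformly higher. In control, KO1 and KO2, narrow peaks stood at 90.2%, 82.1% and 73.6% for Flag-actin and 87.6%, 92.4% and 88.0% for BRG1. Wide peaks stood at 8.56%, 10.8% and 7.20% for Flag-actin and 6.55%, 8.78% and 5.66% for BRG1. The IgG lists themselves had 69.5% of the Flag arm peaks in common with the BRG1 arm list.

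**Figure D1:**
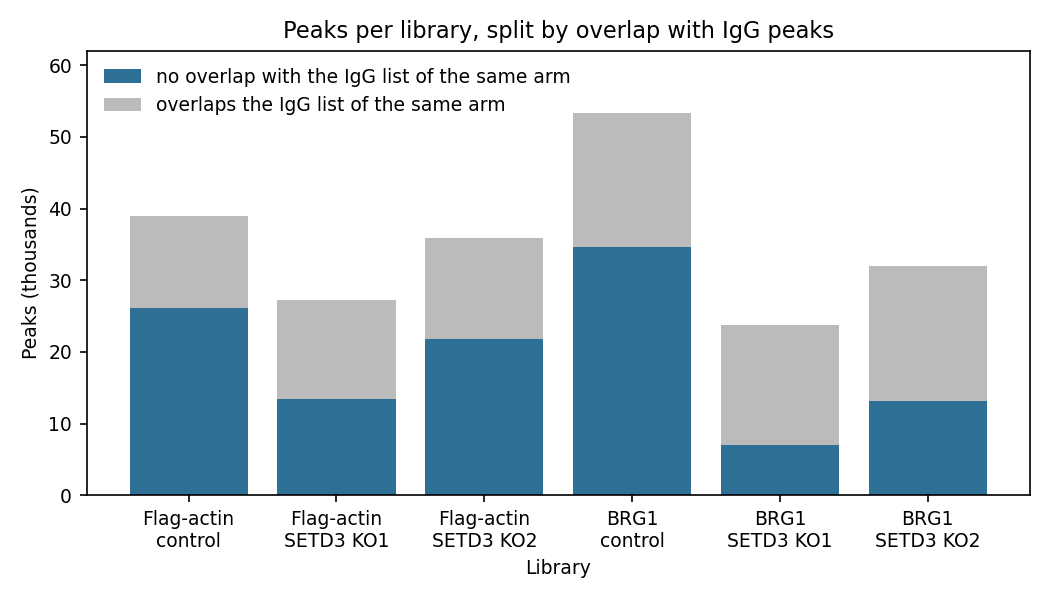
Number of peaks per antibody library, with the part that overlaps the IgG list of the same arm in grey and the rest in blue. The BRG1 KO1 and KO2 libraries hold 7012 and 13220 peaks without IgG overlap, against 34689 in the BRG1 control.

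SETD3 itself, on chromosome 14 from 99397748 to 99486458, held 2 peaks in the Flag-actin control, 3 in Flag-actin KO1 and 11 in Flag-actin KO2. In the BRG1 arm it held 7 peaks in the control and 12 in each KO library. The Flag arm IgG library had 8 peaks there and the BRG1 arm IgG library had 0. Peaks report DNA that was recovered and are no check of whether the knockout removed the protein.

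**Figure D2:**
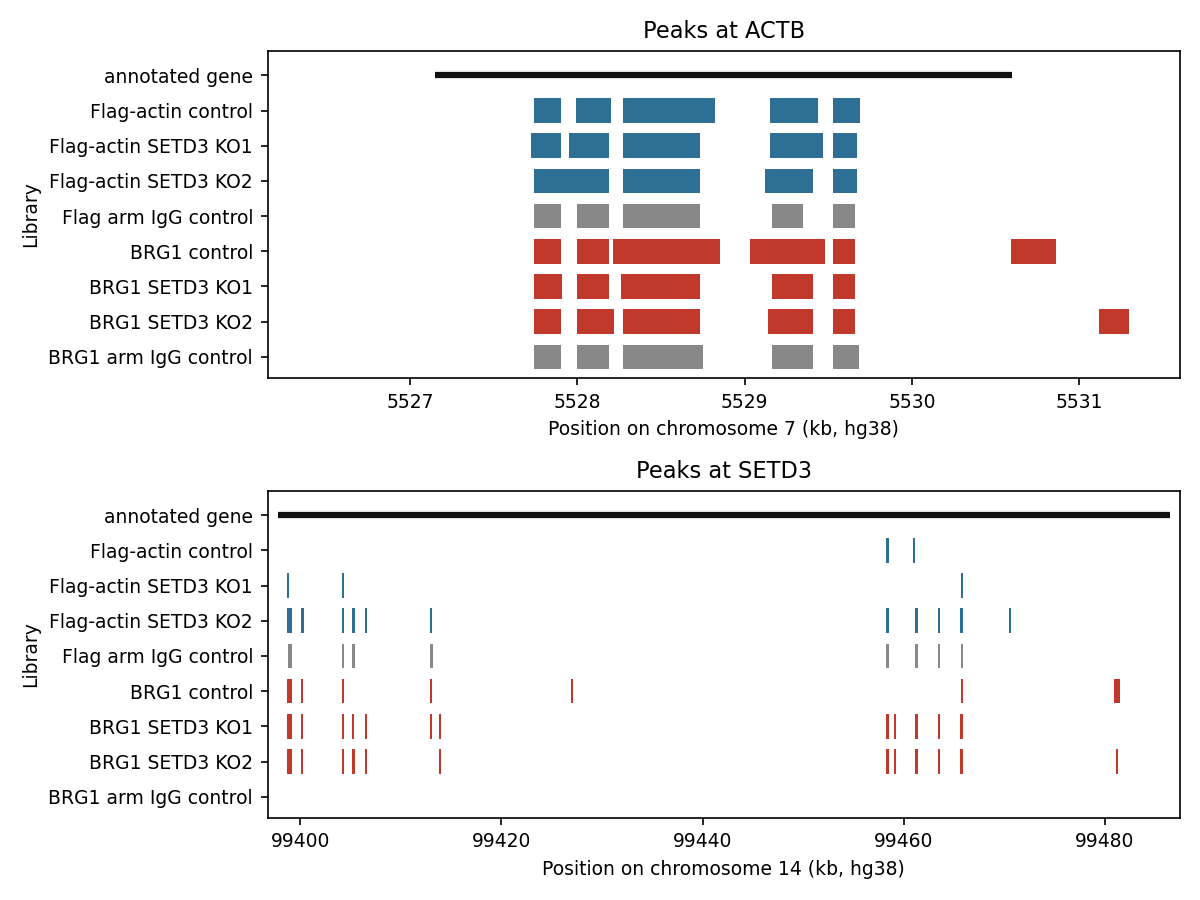
Position of the peaks of each of the 8 libraries at ACTB (top, chromosome 7) and SETD3 (bottom, chromosome 14), in kb, below the annotated gene. ACTB holds blocks at the same places in every library, IgG included, and SETD3 holds 12 peaks in each BRG1 KO library, 8 in the Flag arm IgG library and 0 in the BRG1 arm IgG library.

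The first comparison asked where BRG1 sits with and without SETD3. BRG1 peaks lay at the ends of 6721 of the 20037 protein-coding genes in control cells (33.5%), 1415 in KO1 (7.06%) and 3032 in KO2 (15.1%), against 850 in the IgG library (4.24%). At 4101 genes the control list held a gene-end peak and neither KO list did, and at 76 genes both KO lists held a peak and the control did not. A loss needs absence from both KO lists and a gain presence in both, so these counts are not alike. Against KO1 alone 5581 genes were lost and 275 gained, and against KO2 alone 4418 and 729. Genes of the translation machinery were among those with fewer peaks: 41 of 79 cytosolic ribosomal protein genes had a gene-end BRG1 peak in the control, 3 in KO1 and 14 in KO2. Extracellular matrix and laminin genes had 17 of 48 in the control, 4 in KO1 and 3 in KO2. With every list shortened to the length of the shortest, the genes lost in both numbered 1814 and those gained in both 128.

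The strongest control peaks without a KO peak lay at SLC27A1, a fatty acid transporter (chromosome 19, 17469631 to 17470560, total signal 28660), GPRC5A, an epithelial orphan receptor (chromosome 12, 12890811 to 12891570), and RNF43, a ubiquitin ligase that restrains Wnt receptors (chromosome 17, 58417501 to 58418000). They were followed by PRR11, ODAD1, the secreted chaperone gene CLU, the ERK phosphatase gene DUSP6 (chromosome 12, 89353251 to 89354250), S100A10, a peak shared by ATG12 and AP3S1, and the chromatin reader gene ZMYND8. All 10 ranked at or above the 98.2 percentile of the control list. Among the genes with a peak in both KO lists only, DCAF7 had the highest mean rank, and AURKB, which encodes a mitotic kinase, ranked at the 99.96 percentile in KO1 but the 52.5 percentile in KO2. AURKB held 8 peaks in KO1 and 1 in KO2, and whether they reflect BRG1 occupancy was not tested. DCAF7 ranked at the 92.6 and 96.7 percentiles, on chromosome 17 from 63550121 to 63550420 in KO1. The others by the same rule were DCANP1 with TIFAB, PLEKHH3 with TUBG2, the lysosomal precursor gene PSAP, NANS, TAF11L14, SHMT1, GNG8 and RCN1, of which NANS and GNG8 had their KO1 and KO2 peaks at different places.

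Some sites held BRG1 in all 3 libraries. The highest mean ranks were at DOP1B (chromosome 21, 36156201 to 36156800 in the control), NCF1, MYC, the actin-binding protein gene COTL1 and RELL1. The MYC peak lay just beyond the annotated end of the gene, on chromosome 8 from 127742961 to 127743550 in the control, and ranked at the 99.3, 96.2 and 99.8 percentiles in control, KO1 and KO2. Over MYC and 1 kb around it, the control list held 9 peaks, KO1 3 and KO2 6. CDH1, the E-cadherin gene, held 6 BRG1 peaks in the control, 0 in KO1 and 2 in KO2. ACTG1 held 5, 0 and 1. SMARCA4 held 2, 1 and 1, none at a gene end, and SMARCA2 held 1, 0 and 0.

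Every one of the 21 gene lists had a lower share of genes with a BRG1 peak in the KO mean than in the control. Among translation lists, mitochondrial ribosomal proteins had 40 of 77 genes in the control, 4 in KO1 and 7 in KO2 (KO mean 7.14% ± 2.76, SD, n = 2, against 51.9%), with MRPL34, MRPS15, MRPL1 and MRPS26 lost in both. Cytosolic ribosomal proteins stood at 10.8% ± 9.85 against 51.9%, with RPS6, RPL17 and RPS26 lost in both and RPL8 gained in both. Initiation and elongation factors had 25 of 48 genes in the control, 4 in KO1 and 16 in KO2, and EEF1G, EIF1, EIF3A and EIF3D had no KO peak. Aminoacyl-tRNA synthetases went from 10 of 22 to 0 and 4, with HARS1 and AARS1 among those lost. Ribosome biogenesis went from 27 of 51 to 4 and 7, including NOP10, RRP9 and NCL.

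Adhesion lists showed the same direction. Integrins went from 10 of 26 genes in the control to 2 in KO1 and 6 in KO2, with ITGB1 (chromosome 10, 32958201 to 32958810) and ITGA2 lost in both. Focal adhesion genes went from 19 of 42 to 8 in each KO library, with PTK2, FLNA, TLN1 and ACTN1 lost in both. Adherens junctions and desmosomes went from 14 of 30 to 3 and 7, including NECTIN3, CTNNA1 and CDH3. Tight junction genes went from 12 of 33 to 2 in each, with CLDN3, CLDN4 and CLDN7 lost in both. The extracellular matrix genes lost in both included THBS1, LAMC1 and CCN1.

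The remaining lists had the same direction. Actins and actin regulators went from 36 of 66 genes to 11 and 24, with FSCN1, RHOA, WASF2 and PFN2 lost in both. SWI/SNF subunits went from 13 of 28 to 3 and 5, with SMARCC1, PHF10, ARID2 and DPF1 lost. Immediate early and AP-1 genes had the highest control share, 22 of 25, and 6 and 13 in the KO libraries, with DUSP6, FOS, JUN and IER5 lost in both. Cell cycle genes went from 19 of 37 to 3 and 6, including CDC6, CDK1 and MAD2L1. Wnt targets, with SOX9 and CD44 lost in both, went from 12 of 25 to 3 and 7, and p53 targets, with CCNG1 and PMAIP1 lost in both, from 17 of 26 to 8 and 12. Replication-dependent histones went from 24 of 56 to 7 and 12, epithelial-mesenchymal transition genes from 8 of 23 to 2 and 5, and intestinal differentiation genes from 10 of 34 to 2 and 6. Lists for other cell types held few peaks from the start: fibroblast and immune markers had 2 of 25 in the control, 1 in KO1 and 2 in KO2, and neuron and liver markers 3 of 29, 0 and 3.

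Set against random lists of matched signal, most of these differences lay within the range of other genes with such signal. The matching rank includes both KO libraries, so it can take up part of a difference between KO and control. Matched on the control alone, 3 of 21 lists lay outside. The extracellular matrix and laminin list, with a KO minus control difference of −28.1 percentage points, lay at the 1.89 percentile of random lists and was the 1 list of 21 outside their central 95%. Among 21 lists such a range can leave 1 outside without any difference particular to that list. The percentiles here therefore only describe the lists. The percentile of the extracellular matrix list was 39.5 without KO2, 4.97 without IgG sites and 24.5 with equal-length lists. Within that range, mitochondrial ribosomal proteins (−44.8 points) lay at the 2.505 percentile, cytosolic ribosomal proteins (−41.1 points) at the 4.42 percentile, and initiation and elongation factors (−31.2 points) at the 97.0 percentile. Each left the central 95% in some alternatives: mitochondrial ribosomal proteins with 3 kb windows (2.49), equal-length lists (1.685), lists matched on the control alone (0.770) and without KO1 (1.51), cytosolic ribosomal proteins with 3 kb windows (1.27), and initiation and elongation factors without IgG sites (98.9) and without KO1 (98.1), where the extracellular matrix list stayed outside (2.155). Over the whole gene, a window added after the data were seen, 5 of 21 lists lay outside: cytosolic ribosomal proteins (0.480), ribosome biogenesis (0.280), immediate early and AP-1 genes (0.885), initiation and elongation factors (97.8) and focal adhesion genes (98.9). Matched on the control alone, actins and actin regulators (99.3) and p53 targets (98.1) lay outside as well.

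**Figure D3:**
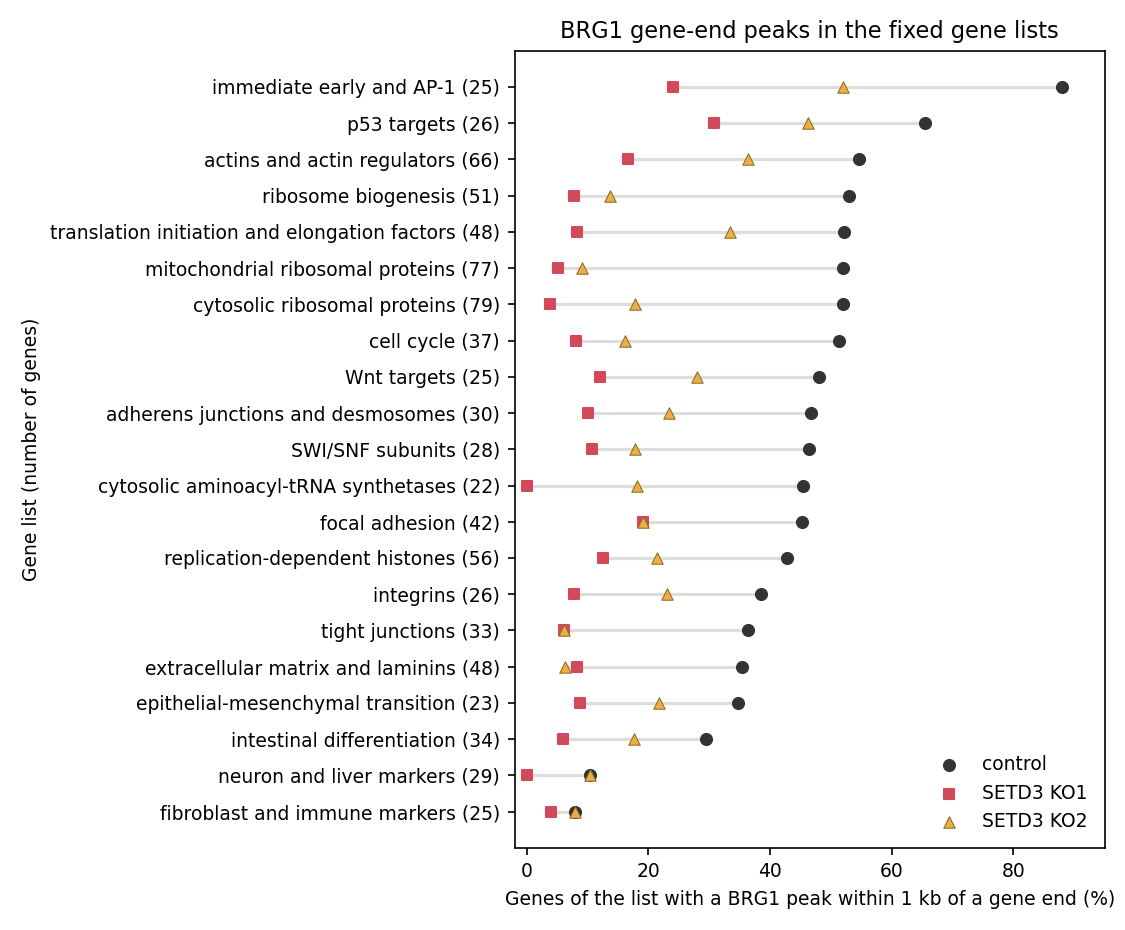
Share of the genes of each fixed list, in percent, with a BRG1 peak within 1 kb of an annotated gene end, in the control (circles), KO1 (squares) and KO2 (triangles), with 1 library per point. The control lies at or above both KO libraries in all 21 lists, from 8% for fibroblast and immune markers to 88% for immediate early and AP-1 genes.

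Over all peaks, 30356 of the 53270 BRG1 control peaks (57.0%, interval 56.6 to 57.4) had no counterpart in either KO list. The share was 67.4% against KO1 and 60.2% against KO2 (63.8% ± 5.10, SD, n = 2). Without peaks that overlapped the IgG list of the same arm the share lost in both was 82.5%, and with equal-length lists 29.8%. With equal-length lists without overlap with either IgG list, added after the data were seen, it was 60.1%. Of 17569 regions held by both KO lists, 1934 had no control peak (11.01%, interval 10.6 to 11.5). Strong control peaks outside IgG sites were kept more often: of those with at least 4 times the lowest total signal of the KO list, 68.5% had a peak in KO1 (interval 63.3 to 73.4, 343 peaks) and 80.2% in KO2 (76.8 to 83.2, 625 peaks), against 16.8% and 21.8% of those above the lowest total signal. For Flag-actin, where every control peak passes 4 times that signal, 4.98% (257 of 5155) and 15.1% (262 of 1730) had a KO1 or KO2 peak at 8 times. These multiples are not alike between the arms. At the sites held by all 8 lists, the median signal ratio was 3.94 in the Flag-actin control against 1.12 and 1.16 in its KO libraries. For BRG1 it was 0.997 in the control against 1.09 and 1.15.

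The second comparison asked where Flag-actin is found with and without SETD3. Flag-actin peaks lay at the ends of 3399 genes in the control (16.96%), 1346 in KO1 (6.72%) and 2229 in KO2 (11.1%), against 826 in IgG (4.12%). At 2311 genes the control list held a gene-end peak and neither KO list did, and at 135 genes both KO lists held a peak and the control did not. A loss needs absence from both KO lists and a gain presence in both, so these counts are not alike. Against KO1 alone 2717 genes were lost and 664 gained, and against KO2 alone 2462 and 1292. Lists of other cell types were among those with fewer peaks: neuron and liver markers had 9 of 29 genes in the control, 0 in KO1 and 1 in KO2. The lists of other cell types were fixed in advance as a background of genes taken to be silent in these cells. In the Flag-actin control each had peaks at a larger share of its genes than the 16.96% of all genes. Flag-actin control peaks were thus not scarcer at such genes. Intestinal differentiation genes had 3 of 34 in the control and 5 in each KO library.

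The strongest control peaks without a KO peak lay at TMEM276 (chromosome 8, 144467951 to 144468970, total signal 120900), KRTAP10-4, a keratin-associated protein gene (chromosome 21, 44573711 to 44574940), and the kinesin gene KIF19 (chromosome 17, 74325641 to 74326130). The next were CYP11B2, which encodes aldosterone synthase, SAMD14, the ceramide synthase gene CERS1, CTDP1, TONSL, PSCA and LOC124905153. TMEM276, TONSL, PSCA and CYP11B2 lie in 1 part of chromosome 8, between 142681081 and 144468970. Of 95 genes with peaks outside the same arm's IgG list in both KO lists only, the highest mean ranks were at IL17F, EVI2A, ATG4A with COL4A6, CEP15, HAPLN1, ZSCAN20, TMEM44, SUV39H2, PANX1 and ACOT12. Each had a peak of up to 50 bp in at least 1 KO list, the width class that mostly overlapped IgG. Overlap with the IgG list of the other arm was not removed here. The IL17F peak, on chromosome 6 from 52235901 to 52235930, was 30 bp wide in both KO lists, and the EVI2A peak, on chromosome 17 from 31321521 to 31321550, likewise.

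Sites in all 3 Flag-actin lists were led by PPP2R2B, where a peak of 60 bp in the control (chromosome 5, 146580961 to 146581020) ranked at the 99.99 percentile in each list. TBX4, IQGAP1, CSH2 and ACTG1 followed. The ACTG1 peak, on chromosome 17 from 81510591 to 81510890 in the control, ranked at the 94.4, 99.5 and 99.4 percentiles. Whether it comes from DNA of the Flag-actin construct, a candidate source at ACTB and at actin pseudogenes (below), was not tested. ACTB, on chromosome 7 from 5527148 to 5530601, held 5 peaks in the control, 5 in KO1 and 4 in KO2, and they made up 2.14%, 2.23% and 2.53% of the summed signal of these lists, against 0.00386% in the Flag arm IgG list. CDH1 held 1, 0 and 1 Flag-actin peaks, MYC 0, 1 and 1, SMARCA4 5, 0 and 3, and SMARCA2 0, 2 and 0.

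Of the 21 lists, 18 had a lower share of genes with a Flag-actin peak in the KO mean, 2 a higher share and 1 the same. Cytosolic ribosomal proteins went from 14 of 79 genes in the control to 5 in KO1 and 11 in KO2, with RPL13, RPS27A, RPLP0 and RPL18 lost in both, and RPL7 and RPL35 with KO1 and KO2 peaks at different places and none in the control. Mitochondrial ribosomal proteins went from 12 of 77 to 6 in each, with MRPS7 and MRPL21 lost, initiation and elongation factors from 10 of 48 to 6 in each, with EIF3G and PABPC1 lost, and ribosome biogenesis from 8 of 51 to 6 in each, with BOP1 lost. Aminoacyl-tRNA synthetases had 1, 0 and 2 of 22. Integrins had 5 of 26 in the control, 0 in KO1 and 1 in KO2, with ITGB4 and ITGA5 lost, and focal adhesion genes 8 of 42, 2 and 3, with ACTN4 lost. Adherens junctions and desmosomes had 7 of 30, 1 and 3, with CDH1 and PERP lost, and tight junctions 5 of 33, 1 and 3. Extracellular matrix and laminins had 12 of 48, 5 and 6, with COL6A1, COL6A2 and LAMC1 lost.

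Actins and actin regulators held Flag-actin peaks at 12 of 66 genes in the control, 9 in KO1 and 14 in KO2, with CORO1B, EZR and PFN1 lost in both, and MYH9 with KO1 and KO2 peaks at different places and none in the control. SWI/SNF subunits had 6 of 28, 3 and 5, replication-dependent histones 8 of 56, 4 and 4, Wnt targets 5 of 25, 1 and 4, p53 targets 4 of 26, 3 and 3, cell cycle genes 10 of 37, 1 and 7, epithelial-mesenchymal transition genes 7 of 23, 3 and 1, immediate early and AP-1 genes 3 of 25, 3 and 4, and fibroblast and immune markers 5 of 25, 1 and 1. Neuron and liver markers (−29.3 points, with TUBB3, RBFOX3, APOA1 and SNAP25 lost in both) lay at the 0.405 percentile of random lists, but within the central 95% with windows of 3 kb (4.79 percentile) or over the whole gene (7.54 percentile). Intestinal differentiation (5.88 points, with ELF3 peaks in both KO lists at opposite parts of the gene) lay at the 99.3 percentile, but its difference was −2.94 points with windows of 3 kb, and its percentile was 93.6 without KO1. The other 19 lists lay within the central 95%, but not under every alternative. With equal-length lists actins and actin regulators had 7 of 66 genes in the control, 9 in KO1 and 11 in KO2 (4.55 points, 99.4 percentile), and integrins 4 of 26, 0 and 0 (−15.4 points, 1.025 percentile). Matched on the control alone these lists lay at the 99.5 and 0.660 percentiles, and without IgG sites fibroblast and immune markers (5 of 25 genes in the control, 0 and 0 in the KO libraries) lay below that range. Whether peaks at the actin genes among the actins and actin regulators come from DNA of the construct was not tested.

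Over all peaks, 24369 of 38902 Flag-actin control peaks (62.6%, interval 62.2 to 63.1) had no counterpart in either KO list, 66.9% against KO1 and 64.4% against KO2 (65.7% ± 1.75, SD, n = 2). Without peaks that overlapped IgG the share lost in both was 91.8%. Of 14598 regions held by both KO lists, 2384 had no control peak (16.3%, interval 15.7 to 16.9). Outside both IgG lists the Flag-actin lists had little in common: 2.63% of control peaks overlapped KO1 (random placement 0.188%), 4.86% overlapped KO2 (0.356%), and 5.37% of KO1 peaks overlapped KO2 (0.168%). The corresponding values for BRG1 were 7.15% (0.0871%), 13.6% (0.171%) and 26.6% (0.114%).

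The third comparison set the difference between control and KO beside the difference between the KO libraries. Of the BRG1 regions held by 1 library, 30356 were in the control only (70.2%), 4312 in KO1 only and 8582 in KO2 only. Alike libraries with lists of equal length would each give 33.3%. The lists held 53270, 23784 and 32038 peaks, and this difference in length alone raises the control-only share. Regions shared by control and KO2 alone (5495) outnumbered those shared by KO1 and KO2 alone (1934) and by control and KO1 alone (1706), and 15617 were in all 3. With equal-length lists the control-only share was 39.8%, and with equal-length lists without IgG sites, an alternative added after the data were seen, it was 31.9%, with 528 regions in KO1 and KO2 alone, 712 in control and KO1 and 1144 in control and KO2. Lists shortened at random, which keeps 6792 of 33618 control peaks and every KO1 peak, had KO1 and KO2 alone above both pairs with the control, with means of 812.4, 333.9 and 354.2. For Flag-actin the control-only share was 43.7% as deposited (24369 regions, against 11855 and 19592 in KO1 only and KO2 only), 36.5% with equal-length lists and 33.3% without IgG sites as well.

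**Figure D4:**
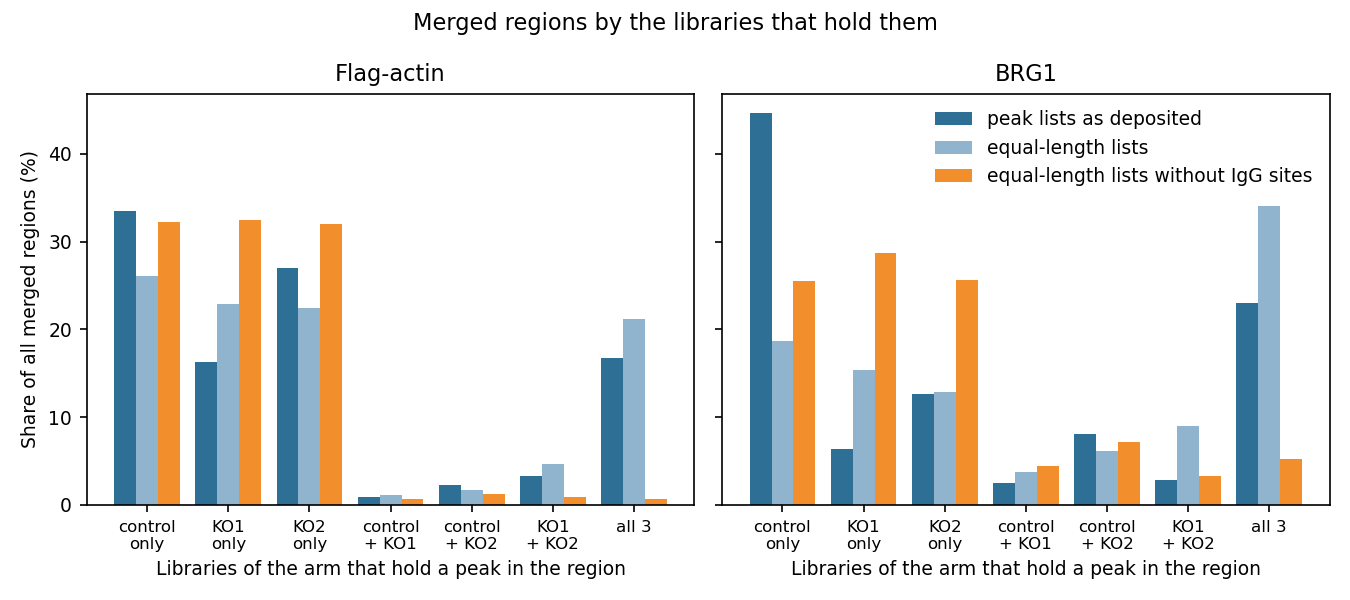
Share of merged regions, in percent of all regions of an arm, by the libraries that hold a peak there, for Flag-actin (left) and BRG1 (right), with lists as deposited, equal-length lists and equal-length lists without IgG sites. In the BRG1 panel the control-only share goes from 44.6% as deposited to 25.5% in equal-length lists without IgG sites, beside 28.7% for KO1 only and 25.7% for KO2 only.

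The fourth comparison concerned sites with both proteins. In control cells 26.5% of BRG1 peaks overlapped a Flag-actin peak (interval 26.1 to 26.8, random placement 0.587%), in KO1 50.4% (49.8 to 51.1) and in KO2 48.7% (48.1 to 49.2). The same BRG1 lists overlapped the shorter Flag arm IgG list in 27.6%, 48.5% and 40.3% of cases. In the control and KO1 the overlap with Flag-actin was therefore close to that with IgG. Outside both IgG lists the shares with a Flag-actin peak were 3.83% (3.63 to 4.04, random 0.561%), 2.37% (2.02 to 2.76, random 0.0975%) and 3.62% (3.30 to 3.96, random 0.195%). Both antibodies had more peaks at gene ends than IgG, which random placement does not keep, so this excess does not by itself show co-occupancy. BRG1 control peaks lost in both KO libraries overlapped a control Flag-actin peak in 7.31% of cases and those kept in 51.8%. Without peaks shared with IgG these values were 3.75% (3.53 to 3.98) and 3.62% (3.16 to 4.12), a difference smaller than its counting error and of the opposite sign.

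The last comparison concerned gene ends. Of the BRG1 peaks, 13.7% had their midpoint within 1 kb of a gene end in the control, 5.48% in KO1 and 8.99% in KO2, against 3.16% in IgG. Without peaks shared with IgG these were 19.3%, 11.04% and 17.4%. For Flag-actin the shares were 8.52%, 4.55% and 5.77%, against 3.70% in IgG, and 10.8%, 5.70% and 7.24% without IgG sites. Elsewhere within genes lay 45.4% of BRG1 control peaks and 52.9% of Flag-actin control peaks.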

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

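The tests on ACTB and on SETD3 were chosen only after these results were seen, as were the lists shortened at random, while the bounds on the lost BRG1 peaks were written before the values they concern, though the equal-length lists without IgG sites were added once other results had been seen.

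ACTB stood out as signal at a gene that no comparison was about. The summed total signal of its peaks was 91320000 in the Flag-actin control, 34630000 in KO1 and 40860000 in KO2, against 46620 in the Flag arm IgG library and between 145600 and 192600 in the BRG1 libraries. Occupancy of the chromosomal gene by Flag-actin as the whole source is argued against by 3 stretches of 70, 300 and 60 bp between the ACTB peaks that no Flag-actin library covers, next to the strongest signal there. DNA of the Flag-actin construct is a candidate source: 13 of 49 actin pseudogene and POTE loci, which resemble ACTB in sequence, held a peak outside both IgG lists in at least 2 Flag-actin libraries, against 1 in the BRG1 libraries. Blocks at the same places lie in all 8 libraries, IgG included, so only the amount of signal is particular to Flag-actin, and weaker occupancy underneath stays open. The Flag arm IgG library is labelled Empty, and whether its cells carried the construct is not given. The contrast with it therefore cannot separate the antibody from the presence of the construct.

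SETD3 peaks in the antibody libraries stood out against 0 peaks in the BRG1 arm IgG library: 12 in BRG1 KO1, 12 in BRG1 KO2 and 11 in Flag-actin KO2. BRG1 occupancy gained at SETD3 when the protein is lost is argued against by the Flag arm IgG library of control cells, where all 8 of its SETD3 peaks overlap a BRG1 KO peak. DNA other than the chromosomal gene and not captured through BRG1 is a candidate source. Both borders lay within 20 bp of a BRG1 KO peak for 5 of these 8 IgG peaks and 8 of the 11 Flag-actin KO2 peaks. This held for 3 of 7 peaks in the BRG1 control, 1 of 3 in Flag-actin KO1 and 0 of 2 in the Flag-actin control. Over all chromosomes, 6374 and 6964 of the 20303 Flag arm IgG peaks had exactly the position of a BRG1 KO1 or KO2 peak. Shared borders alone therefore cannot tell such DNA from shared background. What that DNA was, and why the BRG1 arm IgG library holds none of it, was not tested.

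Many BRG1 control peaks had no peak in the KO libraries, and 3 explanations were weighed, of which none could be excluded. Lower depth of the KO libraries stays open: of the control peaks outside IgG sites with at least 4 times the lowest total signal of a KO list, 68.5% had a peak in KO1 and 80.2% in KO2, and at 8 times 15 of 15 (interval 78.2% to 100%) and 46 of 47 (88.7% to 99.95%). IgG sites filling the KO lists also stays open, because the control-only share met its prediction, 31.9% in equal-length lists without IgG sites, but equal length alone already gave 39.8%, so the length limit and not the IgG sites fixed that outcome. A BRG1 distribution common to both KO lines stays open as well: outside IgG sites, KO1 and KO2 alone held 528 regions against 712 and 1144 with the control in lists shortened by signal, which met the bound written against it, but 812.4 against 333.9 and 354.2 in lists shortened at random (above both in 100 of 100 draws), and neither way is neutral, since the former keeps the strongest 6792 of 33618 control peaks and the latter thins them most. Equal-length lists cannot show a loss at all sites alike, so a global loss of BRG1, antibody yield and depth cannot be told apart here.

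SETD6 held 9 peaks in BRG1 KO2, against 0 in BRG1 KO1, 1 in the BRG1 arm IgG library and 2 in the BRG1 control. AURKB held 8 peaks in BRG1 KO1, against 1 in BRG1 KO2 and 0 in the other 6 libraries. These are short genes, of 8.36 kb for SETD6 and 5.84 kb for AURKB. Whether their peaks come from BRG1 occupancy or from DNA other than the chromosomal gene was not tested.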

How the results depend on the processing

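The alternatives without overlap with either IgG list, alone or with equal length by signal or at random, and windows over the whole gene with 1 kb around it were chosen after the data were seen. No paired analysis was possible because the 1 control library of each antibody leaves no pairs with the 2 KO libraries. All contigs kept every comparison within its spread except the share of control BRG1 peaks with Flag-actin (27.2%). The direction of the gene-end and IgG shares between KO and control held under the few alternatives run for them, from −3.10 to −6.43 points for Flag-actin and −5.05 to −8.90 for BRG1 at gene ends, with −4.35 without IgG sites and −6.43 with 3 kb windows for Flag-actin moved by more than the spread. For gene ends these were removal of IgG sites, the upper part of each list and 3 kb windows. For IgG shares they were the upper part, 50% of a peak covered and all contigs. Neither share was computed on equal-length lists, so the part of list length in them was not tested. Without peaks shared with IgG of the same arm, control peaks lost in both were 91.8% for Flag-actin and 82.5% for BRG1, regions gained in both 62.7% and 27.7%, control-only shares 44.1% and 71.5%, and BRG1 peaks with Flag-actin 3.73% in control and 2.91% in KO. The lost minus kept difference in co-occupancy then turned from −44.5 to 0.132 points. Removal of IgG sites takes sites shared by all lists out by construction. Equal-length lists gave 52.0% and 29.8% lost, 20.9% gained for BRG1, control-only shares of 36.5% and 39.8%, 1537 and 1814 genes lost, 128 genes gained for BRG1, 47.5% and 54.2% co-occupancy and a lost minus kept difference of −51.0 points. The upper part of each list gave 41.8% and 48.6% lost, 6.26% gained for BRG1, control-only shares of 54.0% and 84.5%, 1057 Flag-actin genes lost, 60 and 21 genes gained, 41.0% and 72.8% co-occupancy and −49.6 points. With 50% of a peak covered, 70.0% and 65.9% were lost and 23.1% gained for Flag-actin, with 23.2% and 48.3% co-occupancy and −48.0 points. Sharing within 1 kb gave 55.9% and 50.5% lost, control-only shares of 41.5% and 68.6%, 237 Flag-actin genes gained, 31.0% and 51.2% co-occupancy and −36.9 points. Windows of 3 kb gave 318 and 122 genes gained, and windows of 500 bp 65 and 50. Without overlap with either IgG list, 93.7% and 83.1% were lost, 52.7% and 28.1% gained, control-only shares were 46.0% and 71.3%, 85 Flag-actin genes were gained, co-occupancy was 3.83% and 2.99%, and lost minus kept −0.0508 points. With equal length as well, 92.8% of Flag-actin peaks were lost, 59.2% and 38.9% gained, control-only shares were 33.3% and 31.9%, 1321 and 1336 genes were lost and 61 Flag-actin genes gained, and drawn at random, which by construction thins the longer control list most (6792 of 33618 BRG1 peaks kept), such lists gave control-only shares of 33.5% and 35.3%, with more regions in KO1 and KO2 alone than in either pair with the control in 99 of 100 draws for Flag-actin (means 331.2 against 218.5 and 289.5) and 100 of 100 for BRG1 (812.4 against 333.9 and 354.2). With 1 KO library left out, peaks lost ranged from 64.4% to 66.9% for Flag-actin and from 60.2% to 67.4% for BRG1, regions gained from 52.3% to 61.2% and from 26.3% to 32.8%, genes gained from 664 (without KO2) to 1292 (without KO1) and from 275 (without KO2) to 729 (without KO1), and lost minus kept from −47.9 to −46.0 points, since a gain then needs a peak in 1 KO list only. The control-only share has no value with a KO library left out or with 50% of a peak covered, as it needs 3 libraries and merged regions. Of the single-list differences, 194 stayed within the spread of the KO libraries, 141 moved beyond it, and 1 of a list outside the random range changed sign, intestinal differentiation with Flag-actin at −2.94 points in 3 kb windows. Counting lists inside that range too, 11 values over 7 lists changed sign. The others with Flag-actin were ribosome biogenesis (2.94) and immediate early genes (−6.00) in 3 kb windows, p53 targets (3.85) and actin regulators (4.55) in equal-length lists by signal, again at 3.85 and 1.52 without IgG sites, actin regulators without KO1 (3.03), and tight junctions (3.03) and immediate early genes (−6.00) over the whole gene. With BRG1 it was intestinal differentiation (1.47) in equal-length lists without IgG sites. Where no construction is named, the cause was not tested. How depth limits weak sites was not tested; the lowest total signal that entered a list was 25770 in the Flag-actin control and between 4164 and 6228 in the other antibody libraries.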

Other observations

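The genes and chromosomes in this part were chosen only after their values were seen, and no hypothesis was tested on them.

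BRG1 peaks in control cells were many at a few long genes, counted here within the annotated gene. PCDH7, a protocadherin gene, held 104 BRG1 peaks in the control, 12 in KO1, 27 in KO2 and 3 in the BRG1 arm IgG library. NSMCE2, on chromosome 8 like MYC, held 76, 16, 32 and 5, and the DNA repair gene RAD51B held 58, 16, 12 and 5. SMAD3, a mediator of TGF-beta signalling, held 41, 5, 14 and 0, CUEDC1 42, 10, 8 and 1, and TNIK, a kinase that acts with TCF7L2 in Wnt signalling, 37, 2, 0 and 0. TCF7L2, the main Wnt-responsive transcription factor of the colon, held 38, 11, 17 and 3. VTI1A held 53, 11, 14 and 4, GSE1 48, 12, 20 and 11, and PPP3CA 34, 8, 13 and 1. HMGA2 held 32 peaks in the control, 5 in KO1, 7 in KO2 and 4 in IgG, counted over the gene and 1 kb around it.

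Flag-actin control peaks were many at other genes, counted over the gene and 1 kb around it. ZNF469 held 78 Flag-actin peaks in the control, 12 in KO1, 22 in KO2 and 6 in the Flag arm IgG library. BAHCC1 held 42, 4, 7 and 3, the mechanically gated channel gene PIEZO1 37, 3, 8 and 0, and the collagen gene COL18A1 35, 0, 3 and 1. Chromosomes 16, 17, 19 and 22 held 27.4% of the Flag-actin control peaks outside both IgG lists, 15.5% in KO1 and 19.1% in KO2. For BRG1 they held 17.3%, 12.7% and 15.1%. These chromosomes hold 19.6% of protein-coding genes and 9.26% of the summed chromosome spans.

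Both BRG1 KO lists shared more sites with the Flag-actin KO2 list, which is longer (35892 peaks) than that of KO1 (27249). BRG1 KO1 peaks overlapped Flag-actin KO1 in 50.4% and Flag-actin KO2 in 58.4% of cases, and BRG1 KO2 peaks overlapped Flag-actin KO2 in 48.7% and Flag-actin KO1 in 41.8%.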
